A study of Homo sapiens with 17 samples.

How the data were processed

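RNA, described as poly(A)-selected, was sequenced from H9 cells, a human T cell line that the labels call cutaneous T cell lymphoma cells, and from primary blood mononuclear cells of people with Sézary syndrome, the leukemic form of that lymphoma. Per the labels, cells were harvested after 6 h with vehicle, belinostat or romidepsin, and the treatment note gives 1 µM, which was read as the dose of each drug. The H9 series held 9 libraries (3 per treatment) and the Sézary series 8 (2 vehicle, 3 belinostat, 3 romidepsin), which makes 6 groups and 17 libraries. The malignant cells in the blood samples were not stated to be purified.

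The values deposited by the authors are expected counts per Ensembl gene, 1 table for each series, given as whole numbers. Per the submitters' processing notes, cutadapt 2.3, STAR 2.7.8a, RSEM 1.3.3 and DESeq2 1.32 were used with the GRCh38 (hg38) build, without a role or an order for each. RSEM is the only quantifier named, so the whole numbers were taken as its estimates after rounding. The annotation release and the strand setting of the counting are not given in the sources used here. The H9 series held 60628 entries and the Sézary series 61546, and 60458 gene IDs were in both. Of the entries of each series 5 were marker transgenes, all with 0 counts, and these were left out. Of the Sézary genes 20702 had no symbol, of which 20576 received one through the gene ID. Coordinates were taken from GENCODE 29, on the same build, which held 58516 of the H9 gene IDs and 58366 of the Sézary gene IDs. All columns of per-sample values were used (0 left out).

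Groups were taken from the sample titles. The Sézary titles give 1 donor code for each treatment, whereas the column names of the table give 1 donor code for each replicate number. The column names were followed, so that each number was taken as a donor. Donors 1 and 2 then had all 3 treatments and donor 3 had no vehicle library. As a check for swapped samples, each of the 8 Sézary libraries was matched to the library with the closest makeup of T cell receptor beta variable segments, and 8 of 8 matched a library of the same donor.

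Total counts, in units of 1e6, ran from 36.6 to 61.6 in the H9 libraries (vehicle 37.3 to 58.5, belinostat 37.7 to 61.6, romidepsin 36.6 to 37.3) and from 27.8 to 45.5 in the Sézary libraries (vehicle 39.7 to 41.5, belinostat 28.4 to 45.5, romidepsin 27.8 to 30.4). At that depth 3 counts equal 0.0487 to 0.0820 counts per 1e6 counts (CPM) in H9 and 0.066 to 0.108 CPM in the Sézary libraries. Replicates of the same group differed by more than counting noise, with a chi-square per gene of 8.86 to 88.2 in H9 and 153 to 299 in the Sézary series. The spread was therefore estimated from the replicates, as a biological coefficient of variation of 22.9% in H9 and 63.6% in the Sézary cells. Protein-coding genes took 91.4% to 93.4% of the counts in H9 and 89.7% to 92.3% in the Sézary libraries, mitochondrial genes 0.634% to 2.01% and 0.613% to 2.31%, and RN7S and RNase P RNA genes 4.03% to 6.03% and 3.79% to 6.31%. The latter RNAs usually carry no poly(A) tail, so the selection may have been incomplete, and histone gene counts may include transcripts without a tail. Hemoglobin genes took at most 0.0138%.

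Each series was fitted alone with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr (18557 in H9, 21265 in the Sézary cells), libraries were scaled by TMM, and 1 fit held all 3 treatments of a series without a block. Each contrast was tested by the robust quasi-likelihood F-test, two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Fold changes are log2 values of that fit, and each standard error (SE) is the absolute log2 fold change divided by the square root of its F statistic. CPM values are TMM-scaled means with the standard deviation (SD) between libraries. The contrasts were belinostat against vehicle, romidepsin against vehicle, and romidepsin against belinostat, in each series. The difference of each drug's effect between the Sézary cells and H9 was tested as an interaction in 1 fit of all 17 libraries over 23196 genes. Intervals for the difference of the drugs are 95% intervals from the SE and the residual degrees of freedom. Where a gene had 0 counts in a whole group, its fold change was also computed with a floor of 3 counts over the group and is a bound.

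The agreement of both drugs within a series was given as Pearson's r and the covariance over genes, beside 100 simulations in which no gene changed and both drugs shared the vehicle libraries. A second set of 100 simulations, added after the results were seen, also held the replicate or donor effects of the blocked fit. The agreement of H9 with the Sézary cells was given as Pearson's r and Spearman's rho over genes and as overlaps of calls beside those of chance.

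The 33 gene lists with 566 entries were written before the data were examined, as were the tests, the alternatives named below and the rule for the genes named. They were GATA-3 and type 2 helper genes, T cell receptor and co-receptor signaling, T cell transcription factors, Sézary cell marker genes, immune checkpoint and costimulatory receptors, cytokines and chemokines, common gamma chain cytokine receptor and JAK-STAT genes, NF-kB pathway and target genes, zinc-dependent histone deacetylases, histone acetyltransferases and acetyl-lysine readers, genes raised by deacetylase inhibitors in other cells, histone genes with polyadenylated transcripts, neuronal genes, MYC and ribosome biogenesis genes, DNA replication and E2F genes, mitosis genes, cyclin-dependent kinase inhibitors and D cyclins, death-promoting BCL2 family and death receptor genes, death-opposing BCL2 family and IAP genes, p53 target genes, immediate-early genes, unfolded protein and integrated stress response, heat shock proteins, MHC class I and antigen processing, MHC class II, ABC drug transporters, and markers of monocytes, B cells, natural killer cells, CD8 T cells, platelets, erythroid cells and neutrophils. Lists were tested with camera of limma 3.58.1 on voom values with a preset correlation of 0.01, with an estimated correlation, and with fry, each adjusted over the lists. Members past the threshold were counted over all genes tested and adjusted over the list alone. A list median is the median log2 fold change of its tested members.

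The genes named were GATA3, 12 anchor genes fixed beforehand, and the 5 largest rises and 5 largest falls among genes past the threshold with a mean of at least 10 CPM, a usual symbol and no overlap between the libraries of both groups. From each list up to 3 of the largest members past the threshold with at least 1 CPM, and the largest in the other direction, could be named. Not every gene that this rule allowed is reported. Lack of overlap arises by chance in 10% of genes for 3 against 3 libraries and in 20% for 2 against 3. XIST, Y-linked genes and the variable, diversity and joining segments of T cell receptors and immunoglobulins were kept out of the gene tables (26 genes in H9, 56 in the Sézary cells), since they can mark a person.

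Replicate numbers come from the H9 titles and from the columns of the Sézary table, and whether they pair the libraries was checked once. Over the deviations of each library from its group mean, libraries of the same number correlated at 0.528 to 0.862 in H9 (9 pairs) and at 0.523 to 0.885 in the Sézary series (7 pairs). Libraries of different numbers correlated at -0.734 to 0.562 (18 pairs) and at -0.665 to 0.098 (14 pairs). On 2000 variable genes the second principal component (19.3% of the variance in H9, 34.3% in the Sézary series) lay between the numbers by 97.2% and 99.2%. The numbers therefore pair the libraries in both series, and a fit with the number (replicate or donor) as a block stands beside the unblocked values where a call or a count moved.

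Tests on simulated data held 200 changed genes of 18557 or 21265 for belinostat against vehicle and of 16746 for the belinostat difference between the series. Without a block the H9 fit recovered 43.3%, 77.6% and 84.8% of genes changed by log2 values of 1, 2 and 4, with 1 unchanged gene among 138 called. With the block it recovered 77.6%, 95.5% and 95.5%, with 24 unchanged among 203. The Sézary fit recovered 0%, 0% and 27.3% without a block (0 unchanged among 18) and 17.9%, 52.2% and 92.4% with the donor block (9 unchanged among 117). The test of the difference recovered 0%, 26.9% and 72.7% without blocks (1 unchanged among 67) and 26.9%, 80.6% and 95.5% with them (30 unchanged among 165). The false share depends on how many genes change and does not carry over to real counts. The list test found the 1 moved list of 20 genes and 0 of 20 unmoved lists in each series. Genes that move together were not tested.

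Alternatives set before the data were examined were RLE, upper quartile and no scaling factors, no filter and a filter of at least 5 CPM, the DESeq2 1.42.0 Wald test, limma-voom, fits with only the 2 groups compared, replicate and donor blocks, leaving out each library in turn, a count with an absolute log2 fold change of at least 1, and separate fits for the difference between the series. Alternatives added after the data were seen were H9 replicates 2 and 3 only, the 2 donors with a vehicle library with and without the donor block, DESeq2 with a block, and blocks and left-out libraries for the difference. Random lists of matched expression (10000) served the tests of explanations. Other computing used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.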

Results

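GATA-3, encoded by GATA3, is a zinc finger transcription factor that directs type 2 helper T cells and is carried at high levels by many T cell lymphomas. The data ask whether 6 h of histone deacetylase inhibition lowers GATA3 and the genes that act with it, and whether a T cell lymphoma line and primary Sézary cells answer alike. Belinostat is a hydroxamate and romidepsin a cyclic depsipeptide, so an effect shared by both is less tied to the chemistry of a single compound. Treatment was the leading source of variation in H9 cells, where the first principal component held 74.9% of the variance and lay between treatments by 97.5%. In the Sézary cells it held 45.1% and lay between treatments by 86.9%. Calls come from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. For H9 the p-values measure the spread between samples that the labels do not say come from separate cultures, and for the Sézary cells the spread between 3 donors. Where values or counts stand in pairs, belinostat comes before romidepsin.

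GATA3 (chromosome 10, 8045378 to 8075203, plus strand, GRCh38) fell in H9 cells with both drugs. Its level went from 189 CPM (SD 22.6, n = 3) with vehicle to 100.4 CPM (SD 3.83) with belinostat and 70.9 CPM (SD 11.8) with romidepsin. The changes were -0.92 (SE 0.13, adjusted p = 0.000488) and -1.42 (SE 0.13, adjusted p = 3.02e-05), and both calls held without any single library. In the Sézary cells GATA3 went from 413 CPM (SD 81.8, n = 2) to 126 CPM (SD 56.2, n = 3) and 94.5 CPM (SD 47.3). With romidepsin it fell by 2.13 (SE 0.54, adjusted p = 0.0396), whereas the belinostat value of -1.71 (SE 0.54, adjusted p = 0.0926) did not pass. With the donor as a block the values were -1.36 (adjusted p = 0.00056) for belinostat and -1.80 (adjusted p = 0.000111) for romidepsin. The unblocked romidepsin call was lost without vehicle 1 (adjusted p = 0.0971), vehicle 2 (0.128), belinostat 1 (0.0542), belinostat 2 (0.0569), romidepsin 1 (0.0928), romidepsin 2 (0.0566) or romidepsin 3 (0.0772), and kept only without belinostat 3 (0.0309). GATA3 overlaps GATA3-AS1 on the other strand, and the strand of the counting is not given in the sources used here, so a part of these counts may come from the antisense transcript.

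**Figure D1:**
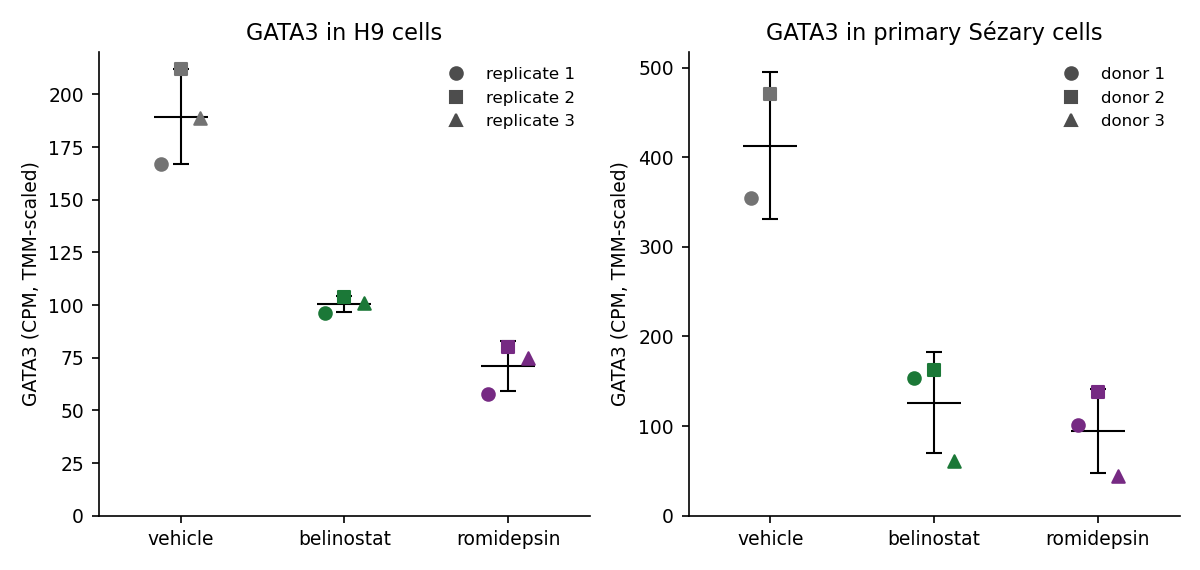
GATA3 in CPM (TMM-scaled, axis from 0) for each H9 library by replicate and each Sézary library by donor, with the mean and SD per treatment. In each system the vehicle libraries sit above all drug-treated libraries, with means of 189, 100.4 and 70.9 CPM in H9 and 413, 126 and 94.5 CPM in Sézary cells.

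Belinostat changed 8165 of 18557 genes in H9 cells, 3995 higher and 4170 lower, of which 1933 and 1571 moved by a log2 value of at least 1. The largest rises were in genes almost silent with vehicle. DACT3, a modulator of Wnt signaling held down by histone marks in colorectal cancer, rose by 6.62 (SE 0.20, adjusted p = 5.33e-07) from 1.27 CPM (SD 0.41) to 124 CPM (SD 9.47). SLC2A4, the insulin-regulated glucose transporter, rose by 5.86 (SE 0.13, adjusted p = 1.72e-07), and EFR3B, SERPINB9 and TUFT1 rose by 4.19, 4.04 and 3.90. The largest falls included the chemokine receptor genes CXCR3 at -4.01 (SE 0.36, adjusted p = 3.38e-05), from 40.4 CPM (SD 1.3) to 2.52 CPM (SD 1.34), and CCR2 at -3.65. They also included the transcription factor gene ASCL4 and the calcium-binding protein gene RCN1 (each -3.66). All of these calls held without any single library.

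Romidepsin changed 9603 genes in H9 cells, 4765 higher and 4838 lower (2815 and 1942 by at least 1). The largest rise was that of RGMA, a guidance molecule of axons, at 8.55 (SE 0.72, adjusted p = 1.66e-05), which went from 0.0731 CPM (SD 0.0329) to 27.2 CPM (SD 12.8). The ectonucleotidase gene ENTPD2 rose by 8.21 (SE 0.56, adjusted p = 5.31e-06), STAC2 by 7.75, HAP1 by 7.47 and the vesicular glutamate transporter gene SLC17A7 by 7.45. CCR2 fell by 5.27 (SE 0.46, adjusted p = 1.95e-05), ASCL4 by 4.69 and CXCR3 by 4.58. NRROS, which anchors latent TGF-beta, fell by 4.15 (SE 0.23, adjusted p = 2.17e-06) from 137 CPM (SD 19.4) to 7.71 CPM (SD 1.12).

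Genes of type 2 helper cells fell along with GATA3 in H9 cells. CCR4, a skin-homing receptor and drug target in this lymphoma, fell by 2.53 with belinostat (SE 0.30, adjusted p = 0.000176) and by 3.56 with romidepsin (SE 0.32, adjusted p = 2.36e-05). Its level went from 223 CPM (SD 49.3) to 38.5 CPM (SD 13.2) and 18.9 CPM (SD 6.16). IL10 fell by 3.73 and 5.09, TOX by 1.23 and 1.76, STAT6 by 0.70 and 0.91, and IL4R by 0.51 and 0.91. The GATA-3 and type 2 helper genes had medians of -0.90 and -1.15 (adjusted p = 0.0282 and 0.0258, but adjusted p = 0.215 and 0.247 with an estimated correlation). Of 15, 2 rose, 10 fell and 3 did not pass, then 2, 10 and 3 (3 and 10, 3 and 10 adjusted over the list alone). IRF4 rose by 3.39 with romidepsin (adjusted p = 0.00136), also higher with belinostat. Sézary cell marker genes did not move as a list, with medians of -0.01 and -0.18 (adjusted p = 0.821 and 0.536). Of 14, 2 rose, 4 fell and 8 did not pass, then 2, 5 and 7 (3 and 4, 2 and 5 adjusted over the list alone, 5 and 6, 5 and 7 with the block).

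T cell receptor signaling genes fell in H9 cells, with medians of -0.65 and -0.85 (adjusted p = 0.000547 and 0.000139, but adjusted p = 0.366 and 0.247 with an estimated correlation). Of 33, 2 rose, 19 fell and 12 did not pass, then 3, 23 and 7 (2 and 21, 3 and 23 adjusted over the list alone). The adaptor gene GRAP2 fell by 2.14 and 2.87 and the phosphatase gene UBASH3A by 2.09 and 2.82. CD247 fell by 1.65 and TEC rose by 0.89 with belinostat, and NFATC1 rose by 1.01 with romidepsin. In CPM each moved the same way with the other drug. T cell transcription factors split, with medians of -0.37 and -0.61 (adjusted p = 0.224 and 0.0723). Of 32, 9 rose, 14 fell and 9 did not pass, then 10, 18 and 4 (10 and 15, 10 and 19 adjusted over the list alone). IKZF1 fell by 2.29 and 2.93, while the chromatin organizer gene SATB1 rose by 3.71 and 3.55.

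Cytokine and NF-kB genes fell in part in H9 cells. IL2 fell by 2.94 and 3.73, LIF by 2.92 and 3.40, BCL3 by 2.09 and 3.09 and TRAF1 by 1.70 and 2.43. Cytokines and chemokines had medians of -1.0 and -1.18 (adjusted p = 0.0662 and 0.0585, and 0.0204 and 0.00692 with the block). Of 15, 1 rose, 5 fell and 9 did not pass, then 1, 7 and 7 (the same adjusted over the list alone, 1 and 9, 2 and 11 with the block). Common gamma chain and JAK-STAT genes did not move as a list, with medians of -0.35 and -0.57 (adjusted p = 0.654 and 0.432). Of 21, 5 rose, 7 fell and 9 did not pass, then 4, 8 and 9 (5 and 7, 5 and 11 adjusted over the list alone, 6 and 13 for romidepsin with the block). IL15RA fell by 1.33 and 1.73 and PIM2 rose by 1.20 and 1.25. NF-kB genes had medians of -0.20 and -0.32 (adjusted p = 0.245 and 0.163). Of 15, 1 rose, 6 fell and 8 did not pass, then 1, 6 and 8 (2 and 6, 1 and 6 adjusted over the list alone, 4 and 7, 4 and 8 with the block). Immune checkpoint receptors held no common direction, with medians of -0.17 and 0.44 (adjusted p = 0.934 and 0.697). Of 10, 3 rose, 2 fell and 5 did not pass, then 4, 3 and 3 (4 and 2, 4 and 3 adjusted over the list alone, 4 and 4 for belinostat with the block). TNFRSF8, which encodes CD30, fell by 2.38 and 3.22, and VSIR rose by 1.89 and 1.90.

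Genes known to rise under deacetylase inhibitors in other cells rose in H9, with medians of 0.99 and 1.56 (adjusted p = 0.000812 and 0.000342, but adjusted p = 0.179 and 0.132 with an estimated correlation). Of 19, 11 rose, 1 fell and 7 did not pass, then 13, 2 and 4 (11 and 1, 15 and 2 adjusted over the list alone). CDKN1A, which encodes the cell cycle inhibitor p21, rose by 2.67 (SE 0.24, adjusted p = 3.7e-05) and 2.86 (SE 0.24, adjusted p = 1.76e-05). Its level went from 6.07 CPM (SD 1.51) to 38.6 CPM (SD 7.17) and 44.0 CPM (SD 10.3). TUBB3 rose by 2.14 and 2.33, while KLF6 fell by 0.71 and 1.00. TXNIP did not pass with belinostat (-0.03, adjusted p = 0.768) and fell by 0.22 with romidepsin (adjusted p = 0.0281, up to 0.108 without a single library). The drug transporter gene ABCB1 did not pass (1.37 and 1.65, adjusted p = 0.145 and 0.0767, and 0.00221 and 0.000341 with the block).

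Acetyltransferase and acetyl-lysine reader genes fell in H9 cells, with medians of -0.75 and -0.80 (adjusted p = 0.000596 and 0.00101, but adjusted p = 0.215 and 0.247 with an estimated correlation). Of 19, 2 rose, 12 fell and 5 did not pass, then 2, 12 and 5 (2 and 12, 2 and 14 adjusted over the list alone). KAT5 fell by 1.92 and 1.78, and HEXIM1, an inhibitor of the elongation factor P-TEFb, rose by 0.88 and 1.29. Histone deacetylase genes did not move as a list, with medians of 0.08 and 0.11 (adjusted p = 0.314 and 0.413). Of 11, 3 rose, 1 fell and 7 did not pass, then 3, 1 and 7 (the same adjusted over the list alone, 5 and 3 for romidepsin with the block). HDAC11 rose by 3.23 and 3.52 and HDAC5 by 1.10 and 1.39, HDAC7 fell by 1.26 and 1.92, and HDAC1 did not change (0.11 and 0.08, adjusted p = 0.331 and 0.466). Histone genes, whose reads may be shared between near-identical copies, had medians of 0.18 and 0.04 (adjusted p = 0.33 and 0.697). Of 14, 5 rose, 2 fell and 7 did not pass, then 4, 3 and 7 (the same adjusted over the list alone, 8 and 3, 7 and 5 with the block). Neuronal genes rose, with medians of 0.79 and 1.17 (adjusted p = 0.0282 and 0.00319, but adjusted p = 0.373 and 0.247 with an estimated correlation). Of 17, 8 rose, 2 fell and 7 did not pass, then 11, 2 and 4 (the same adjusted over the list alone). Among them CELF3 rose by 2.97 and 3.49.

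MYC fell in H9 cells by 0.87 with belinostat (SE 0.13, adjusted p = 0.000615) and by 2.01 with romidepsin (SE 0.13, adjusted p = 4.98e-06), from 630 CPM (SD 69.4) to 344 CPM (SD 59.9) and 157 CPM (SD 2.98). MYC and ribosome biogenesis genes fell with it, with medians of -0.55 and -0.66 (adjusted p = 0.000547 and 0.000139, but adjusted p = 0.416 and 0.463 with an estimated correlation). Of 25, 1 rose, 14 fell and 10 did not pass, then 1, 17 and 7 (the same adjusted over the list alone). DKC1, of the pseudouridine synthase complex, fell by 1.43 and 1.74. DNA replication and E2F genes did not move as a list in H9, with medians of -0.21 and -0.22 (adjusted p = 0.33 and 0.389). Of 25, 5 rose, 11 fell and 9 did not pass, then 5, 10 and 10 (the same adjusted over the list alone). TK1, the thymidine kinase, rose by 1.60 and 2.16. Mitosis genes did not move either, with medians of -0.11 and -0.17 (adjusted p = 0.33 and 0.294). Of 21, 3 rose, 7 fell and 11 did not pass, then 4, 9 and 8 (the same adjusted over the list alone). FOXM1 fell by 0.97 and 1.12 and PLK1 by 0.92 and 1.23. Inhibitors of cyclin-dependent kinases and D cyclins had medians of 0.46 and 0.10 (adjusted p = 0.224 and 0.617). Of 10, 5 rose, 1 fell and 4 did not pass, then 5, 4 and 1 (5 and 2, 5 and 4 adjusted over the list alone, 6 and 4 for belinostat with the block). CDKN2D, which encodes p19, rose by 2.26 and 2.72.

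p53 target genes rose in H9 cells, with medians of 0.60 and 0.74 (adjusted p = 0.0282 and 0.0489, but adjusted p = 0.215 and 0.247 with an estimated correlation, and 0.0641 for romidepsin with the block). Of 20, 12 rose, 4 fell and 4 did not pass, then 14, 4 and 2 (13 and 5, 14 and 5 adjusted over the list alone). TP53INP1 rose by 2.81 and 2.85, while MDM2 fell by 1.07 with belinostat and FAS by 1.51 with romidepsin, each also lower with the other drug. APAF1 rose by 2.10 and 2.16 and CASP9 by 2.09 and 2.18. Death-promoting genes did not pass as a list, with medians of 0.37 and 0.24 (adjusted p = 0.11 and 0.432). Of 20, 8 rose, 4 fell and 8 did not pass, then 8, 6 and 6 (10 and 4, 8 and 6 adjusted over the list alone). Death-opposing genes had medians of -0.62 and -0.89 (adjusted p = 0.175 and 0.0585, and 0.0396 for romidepsin with the block). Of 8, 1 rose, 4 fell and 3 did not pass, then 1, 5 and 2 (the same adjusted over the list alone). CFLAR fell by 2.06 and 2.25 and BCL2L1 by 1.29 and 2.13, while MCL1 rose by 0.92 and 1.11. BCL2 did not pass with belinostat (-0.07, adjusted p = 0.825) and fell by 0.65 with romidepsin (adjusted p = 0.0294, up to 0.105 without a single library).

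Stress genes differed by class in H9 cells. Immediate-early genes rose, with medians of 0.65 and 1.04 (adjusted p = 0.00787 and 0.00101, but adjusted p = 0.366 and 0.247 with an estimated correlation). Of 20, 8 rose, 0 fell and 12 did not pass, then 13, 1 and 6 (7 and 0, 13 and 1 adjusted over the list alone, 13 and 0 for belinostat with the block). NR4A1 rose by 2.12 and 2.95 and FOS by 1.79 and 2.66. Unfolded protein response genes had medians of 0.32 and 0.35 (adjusted p = 0.224 and 0.238). Of 17, 5 rose, 1 fell and 11 did not pass, then 6, 2 and 9 (2 and 1, 6 and 2 adjusted over the list alone, 11 and 4, 11 and 4 with the block). Heat shock genes had medians of -0.09 and -0.10 (adjusted p = 0.857 and 0.979), while their means were above 0 (0.36 and 0.42). Of 13, 5 rose, 4 fell and 4 did not pass, then 5, 5 and 3 (the same adjusted over the list alone). DNAJB1 rose by 1.39 and 1.79, and HSPA1B, which may share reads with its copy HSPA1A, by 1.67 and 1.70. MHC class I genes did not move, with medians of -0.06 and -0.10 (adjusted p = 0.934 and 0.569). Of 14, 2 rose, 3 fell and 9 did not pass, then 2, 5 and 7 (2 and 3, 2 and 6 adjusted over the list alone, 5 and 4 for belinostat with the block). MHC class II genes had medians of 0.44 and 0.30 (adjusted p = 0.661 and 0.697, and 0.0406 for belinostat with the block). Of 10, 1 rose, 0 fell and 9 did not pass, then 1, 0 and 9 (0 and 0, 0 and 0 adjusted over the list alone, 9 and 1, 9 and 1 with the block). ABC transporter genes had medians of -0.89 and -0.72 (adjusted p = 0.13 and 0.238). Of 4, 0 rose, 3 fell and 1 did not pass, then 0, 3 and 1 (0 and 3, 1 and 3 adjusted over the list alone). ABCC4 fell by 1.49 and 1.43.

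Markers of other blood cells are no measure of cell mixture in a line, and none of their lists passed in H9. Monocyte markers had medians of 0.82 and 1.3 (adjusted p = 0.703 and 0.617). Of 3, 0 rose, 0 fell and 3 did not pass, then 0, 0 and 3 (the same adjusted over the list alone, 1 and 0, 2 and 0 with the block). Natural killer cell markers had medians of -0.43 and -0.59 (adjusted p = 0.47 and 0.346). Of 3, 0 rose, 1 fell and 2 did not pass, then 0, 1 and 2 (the same adjusted over the list alone, 0 and 3, 0 and 3 with the block). CD8 T cell markers had medians of -0.27 and -0.46 (adjusted p = 0.895 and 0.736). Of 5, 0 rose, 0 fell and 5 did not pass, then 0, 0 and 5 (the same adjusted over the list alone, 0 and 2, 1 and 3 with the block). Platelet markers had medians of 0.35 and 0.48 (adjusted p = 0.661 and 0.581). Of 4, 1 rose, 0 fell and 3 did not pass, then 1, 0 and 3 (the same adjusted over the list alone, 2 and 1, 2 and 0 with the block). B cell markers had medians of -0.38 and -0.36 (adjusted p = 0.38 and 0.697). Of 5, 1 rose, 2 fell and 2 did not pass, then 2, 3 and 0 (1 and 3, 2 and 3 adjusted over the list alone). With romidepsin the mean differed in sign from the median for B cell markers (0.71), CD8 T cell markers (0.07) and DNA replication genes (0.01). With belinostat it did so for Sézary marker and checkpoint genes (0.04 and 0.09). The erythroid and neutrophil lists had 1 tested member each in H9, and no list test was run. HBA1, which may share reads with HBA2, rose by 3.47 and 5.00, and CXCR1 by 3.55 and 4.10.

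Compared directly at 6 h, and at 1 µM each if the treatment note holds for both drugs, romidepsin and belinostat differed in 167 H9 genes, 110 higher and 57 lower with romidepsin (63 and 6 by at least 1), and 2623 had an unadjusted p under 0.05. MYC was 1.14 lower with romidepsin than with belinostat on the log2 scale (-1.14, 95% interval -1.46 to -0.82, adjusted p = 0.0156). The transcription factor gene MAFA (2.49, SE 0.27, adjusted p = 0.0152, 23.4 CPM against 4.17), the lactate transporter gene SLC16A3 (2.02, SE 0.22, adjusted p = 0.0152, 85.7 CPM against 21.1) and RGMA (3.10) were higher. GPR15, a homing receptor of T cells (-1.36, SE 0.17, adjusted p = 0.0197), RHOH (-1.32) and BCL11B (-0.73) were lower. GATA3 did not pass (-0.50, interval -0.82 to -0.18, adjusted p = 0.123) but did with the replicate block (-0.51, adjusted p = 0.0002). CCR4 (-1.03, -1.75 to -0.30), TOX (-0.53, -0.81 to -0.25), IL4R (-0.40, -0.67 to -0.13), BCL2 (-0.58, -1.10 to -0.06), STAT6 (-0.21, -0.51 to 0.10) and TXNIP (-0.19, -0.36 to -0.02) likewise passed with the block (adjusted p = 2.3e-06, 0.000133, 0.00102, 3.1e-05, 0.0194 and 0.0295). CDKN1A (0.19, -0.36 to 0.74), ABCB1 (0.28, -1.28 to 1.84) and HDAC1 (-0.03, -0.23 to 0.17) did not pass with or without the block. The block raised the count to 4047, and in the simulation of belinostat against vehicle 24 of 203 blocked calls were false. Upper quartile scaling gave 136 higher and 42 lower. The count was 218, 81 and 48 without vehicle 1, 2 and 3, 13, 30 and 0 without belinostat 1, 2 and 3, and 101, 0 and 0 without romidepsin 1, 2 and 3, so no single gene call held throughout.

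As lists, T cell genes lay lower and inducible genes higher with romidepsin than with belinostat in H9. T cell receptor signaling genes had a median of -0.21 (adjusted p = 5.53e-05, but adjusted p = 0.251 with an estimated correlation). Of these 0 were higher, 2 lower and 31 not past (1 and 6 adjusted over the list alone, 1 and 15 with the block). T cell transcription factors had the same median (adjusted p = 5.53e-05, but adjusted p = 0.122 with an estimated correlation), with 0, 5 and 27 genes (0 and 11 adjusted over the list alone, 3 and 13 with the block). Genes raised by deacetylase inhibitors had a median of 0.41 (adjusted p = 0.00239, but adjusted p = 0.122 with an estimated correlation), with 3, 0 and 16 genes (4 and 0 adjusted over the list alone, 9 and 1 with the block). Among them DHRS2 was higher by 2.02. Neuronal genes had a median of 0.37 (adjusted p = 0.00239, but adjusted p = 0.268 with an estimated correlation) and 0 members past (3 and 0 adjusted over the list alone, 8 and 0 with the block). Immediate-early genes had a median of 0.30 (adjusted p = 0.00239, but adjusted p = 0.251 with an estimated correlation) and 0 members past (0 adjusted over the list alone, 7 and 0 with the block). MYC and ribosome biogenesis genes lay lower with a median of -0.08 (adjusted p = 0.013, but adjusted p = 0.672 with an estimated correlation), with 0, 1 and 24 genes (0 and 2 adjusted over the list alone, 0 and 8 with the block). With the block the GATA-3 list passed as well (0.0162 against 0.0535), as did the Sézary marker (0.0077 against 0.0542) and cytokine lists (0.0077 against 0.114). So did the death-promoting (0.0285 against 0.0736), death-opposing (0.032 against 0.0819) and MHC class I lists (0.0243 against 0.114), and none of the others.

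In the Sézary cells belinostat changed 1700 of 21265 genes, 795 higher and 905 lower (782 and 887 by at least 1). H4C15, a histone H4 gene whose counts may be shared with its copies, rose by 5.53 (SE 0.52, adjusted p = 0.00749). DACT3 rose by 5.84 (SE 0.99, adjusted p = 0.0177) as in H9, and DTL, of the replication licensing control, by 5.95 (SE 1.12, adjusted p = 0.0227). GPA33, a surface glycoprotein of resting T cells and gut epithelium, fell by 6.66 (SE 0.57, adjusted p = 0.00749) from 72.6 CPM (SD 15.3) to 0.716 CPM (SD 0.198), and IGHM, the heavy chain of immunoglobulin M, by 6.28 (SE 0.63, adjusted p = 0.00749). STAT6 fell by 1.81 (SE 0.37, adjusted p = 0.03). MYC (-2.78), CCR4 (-2.47), IL4R (-1.54), TOX (-1.58) and BCL2 (-1.30) did not pass (adjusted p = 0.0696, 0.0614, 0.0633, 0.0612 and 0.284), and all passed with the donor block (0.000731, 0.011, 0.0131, 0.000523 and 0.00833). CDKN1A (-0.04, adjusted p = 0.984, 44.5 CPM with vehicle), ABCB1 (-0.38, 0.889), HDAC1 (0.18, 0.779) and TXNIP (-0.42, 0.818) passed in neither fit (0% and 17.9% of simulated changes of 1 found). The count was 7508 with the block (9 false of 117 calls in the simulation) and 975 higher and 621 lower without scaling factors. It was 0 and 896 without vehicle 1 and 2, 490, 547 and 389 without belinostat 1, 2 and 3, and 1152, 1062 and 1022 without romidepsin 1, 2 and 3. No belinostat call in these cells therefore held without vehicle 1.

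Romidepsin changed 2932 genes in the Sézary cells, 1386 higher and 1546 lower (1351 and 1478 by at least 1). TICRR, needed to start replication forks, rose by 6.32 (SE 0.63, adjusted p = 0.00372) from 0.294 CPM (SD 0.126) to 23.7 CPM (SD 5.5), CTXN1 by 7.39 (SE 1.24, adjusted p = 0.0108) and DACT3 by 6.65 (SE 1.03, adjusted p = 0.00819). GPA33 fell by 7.48 (SE 0.59, adjusted p = 0.00347), IGHM by 6.53 (SE 0.64, adjusted p = 0.00372), GIMAP8 by 5.91 and SULT1B1 by 5.80, and these 7 calls held without any single library. CCR4 fell by 3.54 (SE 0.68, adjusted p = 0.0167) from 1265 CPM (SD 566) to 109 CPM (SD 86.8). Falls were also called for MYC by 3.71 (adjusted p = 0.0239), TOX by 2.26 (adjusted p = 0.0157), STAT6 by 2.10 (adjusted p = 0.013) and IL4R by 1.96 (adjusted p = 0.023). Each of these 5 calls was lost without some library (highest adjusted p = 0.0776, 0.156, 0.0594, 0.0619 and 0.133). BCL2 did not pass (-1.76, adjusted p = 0.13, and 0.000753 with the donor block), nor did CDKN1A (0.08, adjusted p = 0.963), ABCB1 (-0.87, adjusted p = 0.703), HDAC1 (0.22, adjusted p = 0.688) or TXNIP (-0.62, adjusted p = 0.693). The count was 8946 with the block, 1675 higher and 1104 lower without scaling factors. It was 886 and 1656 without vehicle 1 and 2, and 1359, 1668 and 1406 without romidepsin 1, 2 and 3. Without scaling factors the median of all genes lay at 0.28 with belinostat and 0.30 with romidepsin, against 0.08 and 0.07.

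T cell identity genes fell in the Sézary cells with both drugs. T cell receptor signaling genes had medians of -1.84 and -2.39 (adjusted p = 3.51e-10 and 2.86e-11, but adjusted p = 0.192 and 0.12 with an estimated correlation). Of 34, 1 rose, 11 fell and 22 did not pass, then 1, 16 and 17 (1 and 19, 1 and 22 adjusted over the list alone, 1 and 26, 1 and 27 with the block). PTPRC fell by 2.83 and 3.89, and LCK, also lower with romidepsin, by 2.87 with belinostat. GATA-3 and type 2 helper genes had medians of -1.71 and -1.79 (adjusted p = 0.00122 and 0.00165, but adjusted p = 0.257 and 0.219 with an estimated correlation). Of 17, 0 rose, 1 fell and 16 did not pass, then 0, 5 and 12 (1 and 5, 1 and 9 adjusted over the list alone, 2 and 11, 2 and 11 with the block). Within donors 1 and 2 the medians of that list were -1.33 and -1.33 with belinostat and -1.81 and -1.23 with romidepsin. T cell transcription factors had medians of -1.54 and -1.75 (adjusted p = 3.5e-07 and 1.55e-08, but adjusted p = 0.135 and 0.12 with an estimated correlation). Of 32, 0 rose, 9 fell and 23 did not pass, then 0, 14 and 18 (0 and 15, 0 and 17 adjusted over the list alone, 1 and 20, 1 and 26 with the block). IKZF1, of lymphocyte development, fell by 2.62 and 3.34. Sézary cell marker genes had medians of -1.23 and -1.31 (adjusted p = 0.00122 and 0.000668, but adjusted p = 0.192 and 0.12 with an estimated correlation). Of 17, 0 rose, 2 fell and 15 did not pass, then 0, 6 and 11 (0 and 6, 0 and 7 adjusted over the list alone, 0 and 8, 2 and 11 with the block).

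The lists of monocyte, natural killer cell and CD8 T cell markers passed as lower beside these genes, with few single members past, and those of B cells, platelets, erythroid cells and neutrophils did not pass. Monocyte markers had medians of -1.76 and -2.32 (adjusted p = 0.00122 and 0.000859, but adjusted p = 0.465 and 0.379 with an estimated correlation). Of 14, 0 rose, 2 fell and 12 did not pass, then 0, 3 and 11 (0 and 3, 0 and 5 adjusted over the list alone, 0 and 8, 0 and 11 with the block). CSF1R, the receptor of macrophage colony-stimulating factor, fell by 2.67 and 3.34. Natural killer cell markers had medians of -1.96 and -2.05 (adjusted p = 0.0175 and 0.0484, but adjusted p = 0.347 and 0.379 with an estimated correlation). Of 8, 0 rose, 1 fell and 7 did not pass, then 0, 1 and 7 (0 and 2, 0 and 2 adjusted over the list alone, 0 and 5, 1 and 5 with the block). CD8 T cell markers had medians of -2.26 and -2.24 (adjusted p = 0.0163 and 0.0484, but adjusted p = 0.257 and 0.369 with an estimated correlation, and 0.0855 for romidepsin with the block). Of 4, 0 rose, 0 fell and 4 did not pass, then 0, 0 and 4 (0 and 1, 0 and 0 adjusted over the list alone, 0 and 3, 0 and 2 with the block). B cell markers had medians of -0.93 and -0.53 (adjusted p = 0.254 and 0.703). Of 6, 0 rose, 0 fell and 6 did not pass, then 0, 0 and 6 (the same adjusted over the list alone, 0 and 1, 0 and 1 with the block). Platelet markers had medians of 0.31 and 0.38 (adjusted p = 0.961 and 0.635). Of 7, 0 rose, 0 fell and 7 did not pass, then 0, 0 and 7 (the same adjusted over the list alone, 1 and 0, 1 and 0 with the block). Erythroid markers had medians of -0.32 and -0.37 (adjusted p = 0.96 and 0.703). Of 5, 0 rose, 0 fell and 5 did not pass, then 0, 0 and 5 (the same adjusted over the list alone). Neutrophil markers had medians of -0.76 and 0.23 (adjusted p = 0.96 and 0.703). Of 3, 0 rose, 0 fell and 3 did not pass, then 1, 0 and 2 (1 and 0, 1 and 0 adjusted over the list alone, 1 and 1, 1 and 1 with the block). The mean differed in sign from the median for erythroid markers (0.13 and 0.41), for neutrophil markers with belinostat (0.63) and for B cell markers with romidepsin (0.23). Platelet markers with belinostat had a downward camera direction with a median above 0.

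MHC class I genes fell in the Sézary cells, with medians of -1.43 and -1.66 (adjusted p = 2.76e-08 and 1.04e-08, but adjusted p = 0.066 and 0.0752 with an estimated correlation). Of 14, 0 rose, 6 fell and 8 did not pass, then 0, 9 and 5 (0 and 10, 0 and 13 adjusted over the list alone, 0 and 13, 0 and 14 with the block). The immunoproteasome gene PSMB8 fell by 2.74 and 3.41 and the peptide transporter gene TAP1 by 2.08 and 2.72, while HLA reads may be shared between copies. Checkpoint receptors had medians of -1.77 and -2.24 (adjusted p = 0.00038 and 0.000229, but adjusted p = 0.135 and 0.12 with an estimated correlation). Of 17, 0 rose, 2 fell and 15 did not pass, then 0, 5 and 12 (0 and 6, 0 and 7 adjusted over the list alone, 0 and 12, 0 and 13 with the block). TIGIT fell by 3.43 and 5.53, from 464 CPM (SD 285) to 43.1 CPM (SD 27.4) and 10.0 CPM (SD 1.35). Cytokines and chemokines had medians of -1.41 and -1.32 (adjusted p = 0.0119 and 0.0283, but adjusted p = 0.441 and 0.379 with an estimated correlation). Of 17, 0 rose, 1 fell and 16 did not pass, then 0, 1 and 16 (the same adjusted over the list alone, 1 and 13, 0 and 14 with the block). IL16, a T cell chemoattractant, fell by 2.89 and 3.59. Gamma chain and JAK-STAT genes had medians of -0.97 and -1.14 (adjusted p = 0.00812 and 0.00543, but adjusted p = 0.257 and 0.22 with an estimated correlation). Of 22, 0 rose, 1 fell and 21 did not pass, then 1, 3 and 18 (1 and 3, 1 and 3 adjusted over the list alone, 2 and 13, 3 and 13 with the block). NF-kB genes had medians of -0.63 and -0.54 (adjusted p = 0.0698 and 0.0516, and 0.00724 and 0.00605 with the block). Of 18, 0 rose, 0 fell and 18 did not pass, then 0, 1 and 17 (0 and 0, 0 and 0 adjusted over the list alone, 0 and 9, 0 and 9 with the block). MHC class II genes had medians of -0.69 and -1.05 (adjusted p = 0.102 and 0.0283, the latter adjusted p = 0.412 with an estimated correlation, and 0.0117 for belinostat with the block). Of 10, 0 rose, 0 fell and 10 did not pass, then 0, 0 and 10 (the same adjusted over the list alone, 0 and 4, 0 and 6 with the block).

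Cell cycle genes rose in the Sézary cells, from low levels. DNA replication and E2F genes had medians of 2.32 and 2.67 (adjusted p = 3.19e-10 and 2.17e-10, but adjusted p = 0.066 and 0.0752 with an estimated correlation). Of 25, 11 rose, 0 fell and 14 did not pass, then 16, 0 and 9 (19 and 0, 20 and 0 adjusted over the list alone, 22 and 1 for belinostat with the block). CCNE1, which encodes cyclin E1, rose by 3.44 (SE 0.34, adjusted p = 0.00749) and 3.58 (adjusted p = 0.00372), from 2.96 CPM (SD 0.993) to 32.0 CPM (SD 2.97) and 35.3 CPM (SD 4.31). E2F1 rose by 4.49 and 4.83. Mitosis genes had medians of 3.04 and 3.40 (adjusted p = 3.34e-09 and 1.28e-10, but adjusted p = 0.192 and 0.12 with an estimated correlation). Of 21, 12 rose, 0 fell and 9 did not pass, then 14, 0 and 7 (14 and 0, 16 and 0 adjusted over the list alone). CCNB1, the mitotic cyclin B1, rose by 4.31 (SE 0.37, adjusted p = 0.00749) and 4.51 (adjusted p = 0.00347), from 0.742 CPM (SD 0.0351) to 14.8 CPM (SD 2.0) and 17 CPM (SD 1.86). MYC and ribosome biogenesis genes had medians of 0.50 and 0.42 (adjusted p = 0.00673 and 0.0114, but adjusted p = 0.47 and 0.542 with an estimated correlation), although MYC itself fell with romidepsin. Of 25, 2 rose, 0 fell and 23 did not pass, then 4, 1 and 20 (4 and 1, 5 and 1 adjusted over the list alone, 10 and 2, 10 and 2 with the block). Kinase inhibitors and D cyclins had medians of 0.52 and 0.22 (adjusted p = 0.36 and 0.635). Of 13, 0 rose, 1 fell and 12 did not pass, then 1, 1 and 11 (the same adjusted over the list alone, 4 and 1, 2 and 2 with the block). CDKN1B, which encodes p27, fell by 1.19 and 1.66.

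Acetyltransferase and reader genes fell in the Sézary cells, with medians of -0.76 and -0.82 (adjusted p = 0.00122 and 0.000859, but adjusted p = 0.192 and 0.12 with an estimated correlation). Of 19, 0 rose, 5 fell and 14 did not pass, then 0, 7 and 12 (1 and 8, 1 and 8 adjusted over the list alone, 3 and 10, 3 and 12 with the block). KAT5 fell by 2.48 and 2.27. Histone deacetylase genes had medians of -0.25 and -0.14 (adjusted p = 0.663 and 0.633). Of 11, 1 rose, 2 fell and 8 did not pass, then 1, 2 and 8 (the same adjusted over the list alone, 3 and 2, 3 and 2 with the block). HDAC7 fell by 2.06 and 2.33 as in H9 and HDAC9 by 2.88 and 3.54, while HDAC3 rose by 1.58 and 1.49. Genes raised by deacetylase inhibitors had medians of 0.91 and 1.08 (adjusted p = 0.0226 and 0.00923, but adjusted p = 0.192 and 0.12 with an estimated correlation). Of 20, 1 rose, 1 fell and 18 did not pass, then 4, 1 and 15 (4 and 1, 6 and 1 adjusted over the list alone, 9 and 1, 10 and 1 with the block). CRIP2, a LIM domain gene, rose by 3.39 and 3.58. Histone genes, whose reads may be shared between copies, had medians of 0.86 and 0.68 (adjusted p = 0.0033 and 0.0107, but adjusted p = 0.135 and 0.12 with an estimated correlation). Of 14, 4 rose, 0 fell and 10 did not pass, then 5, 0 and 9 (6 and 0, 5 and 0 adjusted over the list alone, 9 and 1, 8 and 1 with the block). Neuronal genes had medians of 0.75 and 1.74 (adjusted p = 0.161 and 0.0364, the latter adjusted p = 0.199 with an estimated correlation, and 0.0585 for romidepsin with the block), unchanged at the bounds for SNAP25 and SYT1, which had 0 counts in a whole group. Of 23, 0 rose, 0 fell and 23 did not pass, then 0, 0 and 23 (the same adjusted over the list alone, 4 and 2, 10 and 2 with the block).

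Death-opposing genes fell in the Sézary cells, with medians of -1.30 and -1.77 (adjusted p = 0.00812 and 0.00165, but adjusted p = 0.192 and 0.12 with an estimated correlation). Of 9, 0 rose, 2 fell and 7 did not pass, then 0, 3 and 6 (0 and 3, 0 and 3 adjusted over the list alone, 0 and 5, 0 and 5 with the block). CFLAR fell by 2.33 and 3.00 and XIAP by 1.74 and 2.03. Death-promoting genes went in both directions, with medians of -0.04 and -0.28 (adjusted p = 0.96 and 0.703). Of 20, 4 rose, 2 fell and 14 did not pass, then 3, 3 and 14 (4 and 4, 4 and 4 adjusted over the list alone, 5 and 5, 7 and 6 with the block). CASP9 rose by 2.26 and 2.49 and FAS fell by 2.29 and 3.46. p53 target genes did not rise here, with medians of -0.06 and -0.21 (adjusted p = 0.254 and 0.119). Of 21, 0 rose, 2 fell and 19 did not pass, then 0, 3 and 18 (0 and 5, 1 and 6 adjusted over the list alone, 2 and 7, 3 and 6 with the block). Immediate-early genes had medians of -0.12 and 0.30 (adjusted p = 0.96 and 0.371). Of 20, 0 rose, 0 fell and 20 did not pass, then 1, 0 and 19 (0 and 0, 0 and 0 adjusted over the list alone, 3 and 1, 10 and 2 with the block). Unfolded protein response genes had medians of -0.24 and 0.03 (adjusted p = 0.663 and 0.525), with a belinostat mean of 0.08. Of 17, 0 rose, 0 fell and 17 did not pass, then 2, 0 and 15 (0 and 0, 5 and 1 adjusted over the list alone, 5 and 3, 5 and 3 with the block). Heat shock genes rose, with medians of 0.43 and 0.35 (adjusted p = 0.00182 and 0.0059, but adjusted p = 0.196 and 0.219 with an estimated correlation). Of 13, 3 rose, 0 fell and 10 did not pass, then 4, 0 and 9 (4 and 0, 4 and 0 adjusted over the list alone, 6 and 0, 7 and 0 with the block). ABC transporter genes had medians of -0.71 and -0.93 (adjusted p = 0.0501 and 0.0619, and 0.0143 and 0.0219 with the block). Of 7, 0 rose, 0 fell and 7 did not pass, then 0, 2 and 5 (0 and 3, 0 and 3 adjusted over the list alone, 0 and 4, 0 and 4 with the block).

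Directly compared in the Sézary cells, romidepsin and belinostat differed in 0 genes by edgeR without or with the donor block (444 and 2508 at an unadjusted p under 0.05) and by limma-voom. They differed in 12 by the DESeq2 Wald test (8 higher, 4 lower) and in 714 by DESeq2 with the donor block (413 and 301). GATA3 differed by -0.42 (95% interval -1.67 to 0.84), CCR4 by -1.07 (-2.61 to 0.47), MYC by -0.94 (-2.74 to 0.87), IL4R by -0.42 (-1.39 to 0.56), TOX by -0.68 (-1.67 to 0.31) and STAT6 by -0.29 (-1.16 to 0.58). Intervals for CDKN1A (0.12, -1.84 to 2.07), BCL2 (-0.47, -2.08 to 1.14), ABCB1 (-0.49, -3.62 to 2.65), HDAC1 (0.05, -0.70 to 0.79) and TXNIP (-0.20, -2.36 to 1.96) included 0 as well (adjusted p = 1.0 for each of the 11 genes). Lists lower with romidepsin were T cell receptor signaling (median -0.34, adjusted p = 1.89e-07, but adjusted p = 0.292 with an estimated correlation), T cell transcription factors (-0.41, 3.41e-05, but adjusted p = 0.292 with an estimated correlation) and checkpoint receptors (-0.42, 0.0117, but adjusted p = 0.292 with an estimated correlation). So were death-opposing genes (-0.47, 0.00751, but adjusted p = 0.292 with an estimated correlation), MHC class I (-0.31, 0.00338, but adjusted p = 0.292 with an estimated correlation) and Sézary markers (-0.27, 0.046, but adjusted p = 0.443 with an estimated correlation). Higher were mitosis genes (2.27e-05, but adjusted p = 0.391 with an estimated correlation), neuronal genes (0.31, 0.00751, but adjusted p = 0.292 with an estimated correlation), replication genes (0.00751, but adjusted p = 0.292 with an estimated correlation) and immediate-early genes (0.43, 0.00751, but adjusted p = 0.599 with an estimated correlation). With the donor block the gamma chain genes (0.0447), genes raised by deacetylase inhibitors (0.00513), MHC class II genes (0.00127) and monocyte markers (0.000585) passed as well, and none of the other lists did.

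**Figure D2:**
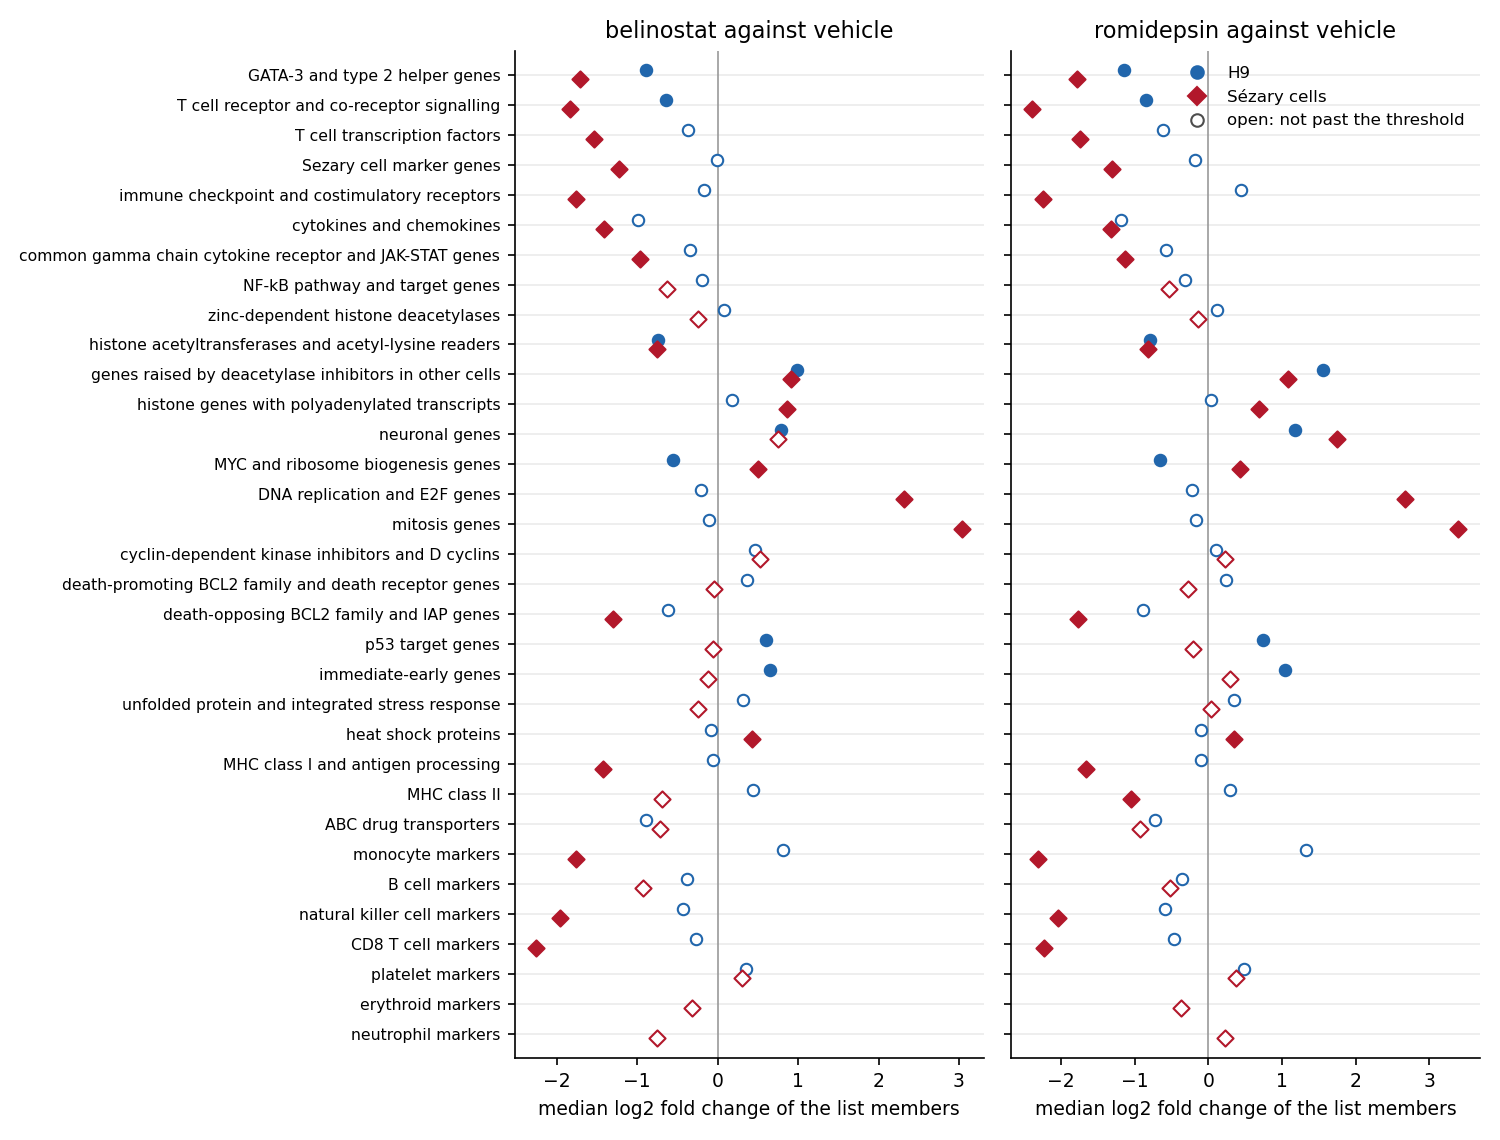
Median log2 fold change against vehicle of each gene list (vertical axis, 1 line per list) for H9 (circles) and Sézary cells (diamonds), belinostat on the left and romidepsin on the right, where filled symbols passed camera with the preset correlation. Mitosis genes stand farthest right in Sézary cells (3.04 and 3.40) and near 0 in H9 (-0.11 and -0.17), while T cell receptor signaling genes lie left of 0 in each system (-1.84 and -2.39, -0.65 and -0.85).

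Both drugs gave nearly the same profile within a system. Their log2 fold changes correlated at r = 0.941 in H9 (covariance 1.21) and r = 0.946 in the Sézary cells (covariance 3.23), against 0.496 (range 0.442 to 0.554, covariance 0.0858) and 0.613 (0.588 to 0.635, covariance 0.80) in 100 simulations where the drugs shared the vehicle libraries alone. With the replicate or donor effects added, the simulated r was 0.499 (0.423 to 0.556) in H9 and 0.774 (0.760 to 0.787) in the Sézary cells, with covariances of 0.0485 and 0.676. In H9 3674 genes were higher and 3848 lower with both, where chance gives 1026 and 1087, and 4 were called in opposite directions. In the Sézary cells 773 were higher and 846 lower with both (51.8 and 65.8 by chance) and 0 opposite. In the simulations without number effects the genes higher, and those lower, with both drugs had a median of 0 and at most 1. With 3 and 2 vehicle libraries the drugs could not each have at least 2 of their own, so a part of the excess in calls may come from the shared controls. H9 and Sézary cells share no libraries, and their fold changes over 16749 genes correlated at r = 0.471 (Spearman's rho 0.492) with belinostat and r = 0.526 (rho 0.548) with romidepsin. With romidepsin 872 genes were higher and 1033 lower in both (347 and 378 by chance), while 57 were higher in H9 and lower in Sézary cells and 74 the reverse (368 and 356 by chance).

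Drug effects in Sézary cells and H9 differed in 1362 genes with belinostat and 2110 with romidepsin (6535 and 7403 with both blocks, with 30 of 165 calls false in the belinostat simulation). CCNB1 did not rise in H9 (129 CPM with vehicle) and rose in Sézary cells, differing by 4.70 (SE 0.23, adjusted p = 1.24e-07) and 4.97 (adjusted p = 6.19e-08). DTL differed by 5.45 (SE 0.78, adjusted p = 0.0011) and 5.69 (adjusted p = 0.000511), and FCMR by -3.68 (SE 0.60, adjusted p = 0.00258) and -4.28. SGSH rose in H9 by 2.06 and 2.31 and differed by -3.10 and -3.71. The CCNB1 and DTL SEs lay below those of the Sézary fit alone. With a shared spread per gene for both systems, these p-values understate the Sézary spread. GATA3 did not pass (-0.83 and -0.68, adjusted p = 0.436 and 0.514), save with belinostat and both blocks (-0.49, 0.0261, romidepsin -0.34, 0.0998). CCR4 (0.03 and 0.05) and the GATA-3 list (medians -1.14 and -1.14, adjusted p = 0.0739 and 0.122) did not pass. Without blocks 0% of simulated differences of 1 were found, so likeness is not shown. CDKN1A (-2.73 and -2.75, adjusted p = 0.0846 and 0.0662), MYC (-1.95 and -1.67, 0.172 and 0.216), STAT6 (-1.15 and -1.16, 0.089 and 0.0688), IL4R (-1.07 and -1.02, 0.155 and 0.149) and BCL2 (-1.26 and -1.09, 0.362 and 0.409) did not pass without the blocks and passed with them (0.000132 and 5.17e-05, 0.00132 and 0.00508, 0.00222 and 0.00156, 0.0404 and 0.0447, 0.00304 and 0.0094), as did HDAC1 with romidepsin (0.18, 0.82 against 0.0495). The belinostat count fell to 853, 855, 824 and 835 without H9 vehicle 2, vehicle 3, belinostat 2 and belinostat 3, and the romidepsin count to 1397, 1375 and 1362 without H9 vehicle 2, romidepsin 2 and romidepsin 3.

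**Figure D3:**
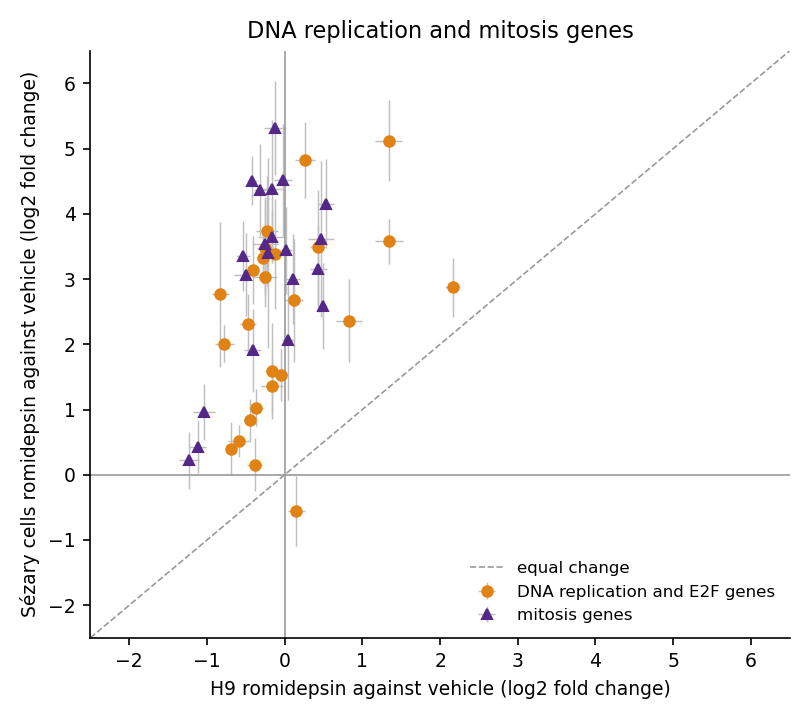
Log2 fold change with romidepsin against vehicle in H9 (horizontal) and in Sézary cells (vertical) for each DNA replication and mitosis gene, with SE bars and a dashed line of equal change. Most genes lie near 0 in H9 and well above 0 in Sézary cells, with medians of -0.22 against 2.67 for replication genes and -0.17 against 3.40 for mitosis genes.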

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

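A test of the difference between the drug effects (Sézary minus H9, log2 scale) singled out 1362 genes with belinostat and 2110 with romidepsin. With a shared spread per gene for both systems, its gene p-values may understate the Sézary spread. The loss of other cells as the whole cause of lower immune genes was a test written after the results were seen. So was the rule that let the spread of the values leave a test open, which moved the monocyte test below from excluded to open. The other tests were written before their values were computed.

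With an estimated correlation 4 lists kept their call in the fit without blocks: T cell transcription factors (-1.04 and -1.48 with belinostat and romidepsin, adjusted p = 0.0233 and 0.0201 with an estimated correlation), DNA replication and E2F genes (2.04 and 2.59, 0.00877 and 0.00768), mitosis genes (3.38 and 3.59, 0.0175 and 0.00907) and MHC class I genes (-1.54 and -1.52, 0.0104 and 0.00907). Without it camera also passed further lists (adjusted p of at most 0.0311 with belinostat and 0.013 with romidepsin) that lost their call. With belinostat these were T cell receptor signaling (-0.96), Sézary markers (-1.29), checkpoint receptors (-1.75), gamma chain genes (-0.74), histone genes (0.21), MYC and ribosome biogenesis genes (0.98), p53 targets (-1.14) and CD8 T cell markers (-2.46), each with adjusted p = 0.139 with an estimated correlation. Immediate-early genes (-0.88, 0.359), heat shock genes (0.54, 0.277) and monocyte markers (-2.33, 0.563) lost it too. With romidepsin the same lists stood at -0.94, -1.39, -2.33, -0.86, 0.42, 1.14, -1.05, -2.19, -1.13, 0.54 and -2.95 (adjusted p = 0.147, 0.147, 0.0683, 0.157, 0.0759, 0.146, 0.147, 0.207, 0.453, 0.284 and 0.461 with an estimated correlation). With both blocks and an estimated correlation none of the 4 lists kept its call (adjusted p = 0.18 and 0.137, 0.156 and 0.1, 0.156 and 0.105, and 0.156 and 0.1 in the order above). With both blocks and the preset correlation immediate-early genes lost their call with romidepsin (0.0601). MHC class II genes (5.96e-05 and 3.46e-05) and natural killer cell markers (0.0194 and 0.025) gained it.

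Among single genes the test singled out, with belinostat, DTL (5.45), TICRR (4.90), CCNB1 (4.70), TPX2 (4.55), KIFC1 (4.34), FCMR (-3.68), TRANK1 (-3.35), TRPV2 (-3.17), SGSH (-3.10) and KALRN (-2.91). With romidepsin it singled out DTL (5.69), TICRR (5.68), HIST1H1B (5.57), KIFC1 (5.07), CCNB1 (4.97), FCMR (-4.28), SGSH (-3.71), SERPINB9 (-3.64), ABCD2 (-3.63) and TRANK1 (-3.53). The SERPINB9 call was lost without H9 vehicle 1 (adjusted p = 0.0679), vehicle 2 (0.0787), belinostat 3 (0.05), romidepsin 2 (0.0858) or romidepsin 3 (0.0872), and without Sézary vehicle 1 (0.0843), vehicle 2 (0.0553), romidepsin 1 (0.0612), romidepsin 2 (0.0549) or romidepsin 3 (0.0769). HIST1H1B reads may be shared with other histone genes.

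DNA replication and mitosis genes stood near 150 CPM in H9 with vehicle and near 1 to 3 CPM in Sézary cells, so their rise could be that of any gene at a low level. Their medians with the donor block were 2.59 and 3.24, at percentile 100 of 10000 random lists matched on vehicle CPM. Those lists had medians of 0.03 and 0.08, so genes at a low level did not rise this far as a class. As random genes were drawn singly and cell cycle genes may move together, the percentile gives no chance level. The rise held over 4 relative scalings (lowest median 2.46), which cannot test total RNA change. A larger share of 1 kind of dividing cell would move all mitosis genes by the same amount, and 23.8% lay far from their median (interval 8.22% to 47.2%, PLK1 0.18 to CDC20 5.29), which leaves it open.

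Markers of monocytes, natural killer cells and CD8 T cells were lower in drug-treated Sézary cells by the test with the preset correlation, and for natural killer cells the difference from H9 did not pass (adjusted p = 0.0638 and 0.0777). A loss of monocytes alone would lower their markers equally, and 25% lay far from their median (interval 3.19% to 65.1%, CSF1R -3.10 to CST3 -0.67), which leaves it open. T cell receptor signaling genes fell with the donor block by a median of at least 2.0 (-2.0) with each drug. A loss of cells that lack these genes would not lower them, so it was not the whole cause of lower immune genes. The malignant cells were not stated to be purified, so the test cannot tell a loss of normal T cells from lower expression.

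Genes with a lower vehicle level rose and those with a higher level fell in both systems, a pattern that no test of a difference singled out. With romidepsin the 20% of genes lowest at vehicle had a median of 0.30 in H9 and 0.58 in Sézary cells, and the highest 20% of genes -0.20 and -0.30. Noise shared by level and fold change was excluded, as Spearman's rho with the level taken from a vehicle library outside the fold change was -0.23. Gene length was excluded with a partial rho of -0.21, close to the bound set beforehand at -0.2. No biological explanation of this pattern was tested.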

How the results depend on the processing

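Most named values kept their direction and their side of the threshold: 6916 of 7849 recomputed values for 394 named genes, 1204 of 1366 for 72 list results and 813 of 882 for 42 differences of genes. The others lost the threshold (813, 162 and 10), gained it (69, 0 and 35) or took the other sign (51, 0 and 24). Of those with the other sign none had passed the threshold in either form. Where the cause of a change is not plain from the smaller number of genes or libraries, the cause was not tested. Depth limits genes near 3 counts, which equal 0.0487 to 0.082 CPM in H9 and 0.066 to 0.108 CPM in the Sézary libraries. Without a Sézary vehicle library the lone one left was assumed to vary like the other groups.

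The replicate block gave 4047 genes for H9 romidepsin against belinostat and 12 lists. The donor block gave 7508 and 8946 genes for Sézary belinostat and romidepsin and a GATA3 value of -1.36 with belinostat. Both blocks gave 6535 and 7403 genes for the difference between the systems, or 5983 and 6874 without donor 3. Apart from these and the calls given beside their results, the 4 lists that lost theirs with an estimated correlation included, the block changed no other call. The DESeq2 Wald test gave 887 (H9 romidepsin against belinostat), 4090 and 5359 (Sézary belinostat and romidepsin), 12 (Sézary romidepsin against belinostat) and a GATA3 value of -1.74 with belinostat. With the blocks it gave 3326, 8505, 9807, 714 and -1.39. Fits with only the 2 groups compared gave 62, 224 and 1507 and a romidepsin GATA3 value of -2.12. Separate fits gave 2146 genes for the belinostat difference. Chosen after the data were seen, the 2 donors with a vehicle library gave 0 and 797 genes, or 5295 and 6813 with the donor block and GATA3 at -1.38. H9 replicates 2 and 3 alone, chosen likewise, gave 1880 genes and 10 lists for romidepsin against belinostat. DESeq2 with a block and the blocks of the difference were also added then.

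Without a filter the drugs correlated at 0.723 (H9) and 0.809 (Sézary) and the systems at 0.253 and 0.317, with 14 and 14 lists past for H9 romidepsin against vehicle and against belinostat. A stricter filter gave 0.56 and 0.60 for the systems and 4 lists for H9 belinostat. With an estimated correlation 0 lists passed in each of the 6 comparisons. By fry 19 and 21 passed for H9 belinostat and romidepsin and 0 for Sézary romidepsin against belinostat.

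Values of genes not past the threshold took the other sign as follows. TXNIP with belinostat in H9 was 0.003 with upper quartile scaling, 0.031 without factors, 0.018 without a filter, 0.008 with a stricter one, 0.018 with 2 groups and 0.022 with replicates 2 and 3. HDAC1, H9 romidepsin against belinostat, was 0.017 (upper quartile) and 0.021 (stricter filter). CDKN1A with belinostat in Sézary cells was 0.046 (upper quartile), 0.105 (no factors), 0.167 (limma-voom), 0.232 (donor block), 0.208 (2 donors with the block) and 0.199 (DESeq2 with the block). ABCB1 there was 0.555, 0.066 and 0.14 (limma-voom, donor block, DESeq2 with the block), and with romidepsin 0.481, 0.098 and 0.015 (limma-voom, 2 donors with the block, DESeq2 with the block). Between the drugs CDKN1A was -0.075, -0.1, -0.074 and -0.076 (limma-voom, donor block, 2 donors with the block, DESeq2 with the block) and ABCB1 0.167 (2 donors with the block). For the difference between the systems CCR4 and HDAC1 were -0.006 and -0.001 with belinostat (RLE), and CCR4 -0.051 and -0.064 with romidepsin (blocks, blocks without donor 3).

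Leaving out each library in turn gave 6758 to 8491 and 8234 to 10029 genes for H9 belinostat and romidepsin, 0 to 218 between them, 0 to 1152 and 886 to 2407 in Sézary cells, and 824 to 1768 and 1362 to 2295 for the difference. GATA3 ran from -1.94 to -1.39 and from -2.49 to -1.80 in Sézary cells. Lists past ran from 8 to 10, 7 to 11 and 6 to 11 in H9 and from 16 to 22, 17 to 22 and 6 to 15 in Sézary cells, and r from 0.898 to 0.940, 0.889 to 0.958, 0.399 to 0.474 and 0.458 to 0.531. SERPINB9 lost its romidepsin difference in 10 of these. Genes not past the threshold that took the other sign ranged as follows. In H9 with belinostat BCL2 ran from -0.235 to 0.137 and TXNIP from -0.086 to 0.01, and between the drugs ABCB1 from -0.351 to 0.801 and HDAC1 from -0.087 to 0.013. In Sézary cells with belinostat CDKN1A ran from -0.752 to 1.466, ABCB1 from -1.334 to 4.04, HDAC1 from -0.06 to 0.445 and TXNIP from -1.409 to 0.0. With romidepsin CDKN1A ran from -0.753 to 1.572, ABCB1 from -1.824 to 3.547 and HDAC1 from -0.012 to 0.491. Between the drugs CDKN1A ran from -0.71 to 0.56, ABCB1 from -0.986 to 0.02, HDAC1 from -0.139 to 0.234 and TXNIP from -1.244 to 0.789. For the belinostat difference CCR4 ran from -0.392 to 0.593, ABCB1 from -2.719 to 2.677, HDAC1 from -0.187 to 0.306 and TXNIP from -1.422 to 0.014. For the romidepsin difference MYC ran from -2.451 to 0.238, CCR4 from -0.799 to 0.608, ABCB1 from -3.427 to 1.969, HDAC1 from -0.038 to 0.454 and TXNIP from -1.411 to 0.071.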

Other observations

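Single genes of other blood lineages rose in the H9 line, although no list of their markers passed there. ITGA2B, a platelet integrin, rose by 5.15 with romidepsin (SE 0.90, adjusted p = 0.00116) from 0.0974 CPM to 3.42 CPM. HBA1 reached 5.31 CPM (SD 1.02) from 0.176 CPM, although its reads may be shared with HBA2. In the Sézary cells IGHM, of B cells, stood at 278 CPM (SD 121) with vehicle and at 3.57 CPM with belinostat, while B cell markers as a list did not pass (median -0.93, adjusted p = 0.254).

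The number of a replicate or donor carried much of the spread. With it as a block the biological coefficient of variation went from 22.9% to 7.26% in H9 and from 63.6% to 25.8% in the Sézary cells. In H9 replicate 1 stood apart in each treatment. The chi-square per gene was 56.2 to 88.2 in pairs of libraries with replicate 1 and 8.86 to 23.2 in those of replicates 2 and 3.

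Of 10 splits of 6 libraries into 3 and 3, 1 reached as many genes for H9 belinostat against vehicle (8165, highest other 0), 1 for romidepsin against vehicle (9603, highest other 0) and 1 for romidepsin against belinostat (167, highest other 1), each the real one. For Sézary romidepsin against belinostat all 10 of 10 had 0 genes. Such splits are too few for a share under 0.05, and all but the real one mix the treatments and hold their effect as spread within the groups.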
